A study of Mus musculus with 4 samples.

How the data were processed

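Single cells sorted from mouse thymus as live CD11c+ cells were measured in 4 libraries, 1 per group: wild type given PBS and wild type with subcutaneous MC38 tumours at 2 weeks, and wild type and Ccr9 knockout with MC38 tumours at 3 weeks. The 2-week libraries form batch 1 and the 3-week libraries batch 2. Per the labels' protocols the libraries were made with 10x Genomics 5' chemistry and read on a DNBSEQ platform. Per the submitters' processing notes the reads were aligned and counted with Cell Ranger 7.1.0 on the mm10 reference. The deposited matrices hold UMI counts per gene and barcode, whole numbers without scaling, for 32285 genes. Per the file headers 3 matrices carry the Cell Ranger metadata line, while that of the knockout library lacks it and lists its entries by gene, so it was written again by another program. Which one, and whether barcodes were filtered, is not stated. The number of mice per library is not given in the labels. Xist was at 187, 204, 331 and 227 CPM in the PBS, 2-week tumour, 3-week wild type and knockout libraries, with Y-linked genes near zero, so all 4 are taken as female.

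The files hold 22036, 20638, 15448 and 15913 barcodes in that order. Cells with at least 500 genes and under 10% mitochondrial UMIs were kept: 21449, 19991, 14947 and 15621, with medians of 9280.0, 8877, 10130.0 and 10343 UMIs. Doublets were called per library with simulated doublets, 2 per cell, scored by nearest neighbours as the Scrublet method does and written for this work, with the threshold at the minimum between the modes of the simulated scores. This removed 2562, 2296, 1308 and 1408 cells, against an expected 17.6%, 16.5%, 12.4% and 12.7% at 0.8% per 1000 barcodes, and left 18887, 17695, 13639 and 14213. Doublets of cells alike in type are not found by this method.

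Counts were scaled to 10000 per cell and logged, 2000 variable genes were taken without Ccr9, sex-linked, immunoglobulin and T cell receptor variable genes, and 30 principal components fed a graph of 20 nearest neighbours clustered with Leiden at resolution 1 on all libraries together, without batch integration. Clusters were named from 15 marker lists: a marker needed a 2-fold higher level and detection in 10% of cells, and a class 3 markers. These thresholds were set after the data were seen, and clusters short of them, with more markers of another class among their top 10 genes, or with no marker of their own class there, stay unnamed. A cluster of the last kind kept its name if cell cycle genes were among its top genes and its depth was not low, as for clusters 10, 13 and 14. Names such as pDC-like describe marker genes and not sorted populations. The 4 dendritic cell classes (cDC1-like, cDC2-like, mature DC-like and pDC-like) hold 14435, 12808, 10717 and 11462 cells.

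For each class and library the counts were summed and given as CPM of the class's sum with exact Poisson intervals, shares with exact binomial intervals, and ratios with 95% intervals from the counts. No test, p-value or number of changed genes was computed, because cells of 1 library are not replicates. A count of 0 was set at 3 counts for ratios. Named genes had at least 20 CPM in either library, a ratio whose interval lay beyond 1.5-fold, and were the 3 largest by the interval's near end in each direction (1 for 3 against 2 weeks); mitochondrial, ribosomal protein, hemoglobin, immunoglobulin, T cell receptor and sex-linked genes and genes of the thymocyte and neutrophil lists were left out of this ranking. Each of 24 gene lists was given by the median log2 ratio of members with at least 20 counts, with at least 5 members, a counting interval from 1000 redraws and a rank among 10000 random lists matched on abundance. Lists are described where the rank was at or below 0.5 or at or above 99.5 and the median at least 0.2 from zero, a rule set after the data were seen; the list of stress genes is given beside them. Of 340 list members 1 had no matching symbol, and 78 entries share a duplicated symbol and were kept apart by gene identifier. Gene positions are GRCm38, from the GENCODE M21 annotation given with the data.

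The method was tested on simulated data: Poisson counts drawn for each class from the mean profile of the compared libraries, at their depths, with known changes in 200 genes. Intervals covered the true ratio in 95.3% to 96.0% of genes, no unchanged gene passed the 1.5-fold bound, and changes of 1.75-fold were recovered in 46% to 98% of genes depending on the class. Since each gene was an independent Poisson draw, such coverage follows from the design of the simulation. Counts that sit mostly in a single cell were not simulated. The check therefore says nothing of that error in intervals, named genes or lists. Of 200 lists without a change, 6 at the depths of the tumour comparison and 9 at those of the knockout comparison fell outside the middle 95% of random lists. The precision is lowest in macrophage-like cells of the 3-week libraries, with 507 and 394 cells.

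Alternatives set before the data were seen were a stricter filter (1000 genes, 5% mitochondrial UMIs), no filter, doublets kept, Leiden resolutions 0.5 and 2, each library clustered on its own, other denominators, median-of-ratios scaling, cells without a UMI of 6 T cell genes, cells thinned to 3000 UMIs, cells weighted equally and list floors of 5 and 100 counts. Added afterwards were a denominator without pDC-like cells, doublets called at the expected rate and removal of the single cell with the most counts of a gene. Tests of explanations for 3 patterns were written down before their values, except those on every barcode, on clusters 4, 10, 13 and 18 and on 0.5 Mb around Ccr9, and except for the resampled interval of the 10 Mb test. Tests of a pattern in Slc15a2 were run and dropped. The Ccr9 level that pDC marker RNA would bring, from the median of 11 marker genes, and the cell cycle list without cluster 26 were computed last. The raw reads and the expression of protein were not analysed here, and values of some genes are not reported here. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2, scikit-image 0.26.0 and matplotlib 3.10.9.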

Results

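Thymic CD11c+ cells from 4 groups of female mice were profiled with 1 library per group: wild type given PBS and wild type bearing MC38 tumours at 2 weeks, and wild type and Ccr9 knockout bearing MC38 tumours at 3 weeks. Ccr9 encodes the receptor for the chemokine Ccl25, which the thymic epithelium makes. The comparisons, cell classes and gene lists were fixed before the values were seen, while the thresholds that name clusters, the rule for which lists are described and the removal of single cells were set afterwards. Every interval covers counting error only, because the variation between mice cannot be measured with 1 library per group. List percentiles rank a list among 10000 random lists of matched abundance and serve as a description of these libraries.

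Ccr9 was measured before any other gene. Over all cells it reached 122 CPM (120 to 124) in the PBS library, 99.7 (98.2 to 101) in the 2-week tumour library, 182 (180 to 184) in the 3-week wild type library and 0.0544 (0.0235 to 0.107), from 8 counts, in the knockout library. The highest level of the compared classes was in plasmacytoid dendritic cell (pDC)-like cells, at 782, 811 and 900.4 CPM in the wild type libraries in the same order. In knockout pDC-like cells no Ccr9 count was found, with an upper limit of 0.899 CPM. With the knockout value set at 3 counts the log2 ratio to wild type was -10.27 there and -4.62 in macrophage-like cells, which also held no count. With the counting error of both libraries, Ccr9 was at least 1002-fold lower in pDC-like and at least 19.6-fold lower in macrophage-like cells. In cDC1-like cells Ccr9 stood at 34.7 CPM in wild type and 0.0340 in the knockout at 3 weeks, from 3 counts (log2 ratio -9.99, -12.27 to -8.45). In cDC2-like cells it stood at 49.0 and 0.0727 CPM, from 1 count (-9.40, -14.70 to -6.91), and in mature DC-like cells at 5.57 and 0.152, from 3 counts (-5.19, -7.49 to -3.61). If all pDC marker RNA in the other classes came from pDC, the same share of pDC RNA would bring 4.47 of 34.7 CPM of Ccr9 in cDC1-like, 21.9 of 49.0 in cDC2-like, 2.79 of 5.57 in mature DC-like and 14.4 of 20.3 in macrophage-like cells of the 3-week wild type library. Expression of Ccr9 by cDC2-like, mature DC-like and macrophage-like cells themselves is therefore left open. T lineage-like cells held 397, 344 and 504 CPM of Ccr9 in the wild type libraries and no count in the knockout library.

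Ccr9 was found in most pDC-like cells and in few macrophage-like or mature DC-like cells. At least 1 Ccr9 UMI was seen in 92.4% (91.5 to 93.2), 91.1% and 91.4% of pDC-like cells in the PBS, 2-week tumour and 3-week wild type libraries, and in 0 of 819 in the knockout library (up to 0.449%). The shares were 8.66%, 7.07%, 10.3% and 0% in macrophage-like cells and 3.46%, 3.99%, 4.88% and 0.125% in mature DC-like cells. Median depths were 12763, 12558, 15597 and 12209 UMIs in cDC1-like cells, 9351.5, 9302, 12662.5 and 9845 in cDC2-like cells, 5220.0, 5023, 6628 and 4810.0 in pDC-like cells, 8419, 8273, 7837 and 8802 in macrophage-like cells and 9161, 8873, 9286 and 7838 in mature DC-like cells. With each cell thinned to 3000 UMIs the shares with Ccr9 were 84.4%, 84.5%, 84.3% and 0% in pDC-like cells, 2.44%, 1.82%, 6.46% and 0% in macrophage-like cells and 1.19%, 1.71%, 1.58% and 0.0436% in mature DC-like cells. Thinning left out 311, 298, 415 and 134 pDC-like cells, 193, 153, 89 and 35 macrophage-like cells and 111, 157, 91 and 110 mature DC-like cells. Of cDC1-like cells 21.6%, 22.6%, 31.6% and 0.0434% held a Ccr9 UMI, and of cDC2-like cells 24.6%, 21.6%, 31.3% and 0.0750%. With thinned cells these were 6.34%, 6.79%, 9.52% and 0.0295% of cDC1-like cells, with 122, 135, 144 and 138 left out, and 9.59%, 9.98%, 11.8% and 0% of cDC2-like cells, with 37, 47, 27 and 20 left out.

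**Figure D1:**
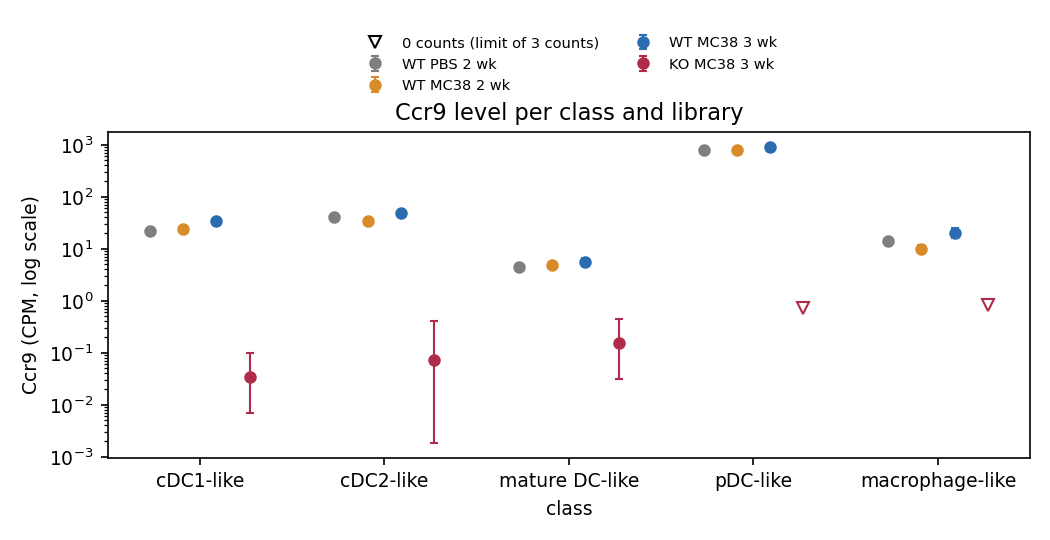
Ccr9 level in CPM of summed counts (log scale) per cell class in the 4 libraries; points are class sums with 95% Poisson intervals. Open triangles mark classes without a Ccr9 count, drawn at the limit of 3 counts.

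Clustering of the 4 libraries together, without Ccr9 among the variable genes, gave 29 clusters. Of the cDC1-like clusters, cluster 0 was led by Xcr1, Naaa and Ppt1, and cluster 11 by Mt3, Cd207 and Itgae. Cycling genes led cluster 10 (Mki67 and Top2a) and cluster 13 (Hmgb2, Ccnb2 and Birc5). Cluster 4 was led by the activation and stress-linked genes Nr4a2, Jdp2, Ahr and Nr4a1, and cluster 18 by Cadm1, Camk1d and Cdk14. The pDC-like clusters 2 and 3 were led by Siglech, Klk1, Ly6d and Cox6a2, cluster 22 by Mctp2, Grm8 and Runx2, and cluster 26 by Ly6d, Cox6a2 and Stmn1. Mature DC-like clusters were led by Ccr7, Fscn1, Ccl22 and Il12b, and cluster 9 of this class was led by Ccl5. The cDC2-like clusters carried Cd209a, Mgl2 and Cd209d, and the macrophage-like cluster Apoe, Lyz2 and the complement genes C1qa, C1qb and C1qc. The largest pDC-like cluster was cluster 3 in the 2-week libraries (50.3% and 47.0% of the class) and cluster 2 in the 3-week libraries (53.6% and 57.9%), while cluster 0 was the largest cDC1-like cluster in each library. Clusters left without a class name, 5 of which met the marker threshold of a class but did not have its markers foremost among their top genes, held 13.2%, 13.6%, 14.8% and 13.6% of cells in the PBS, 2-week tumour, 3-week wild type and knockout libraries. Called doublets, 11.9%, 11.5%, 8.75% and 9.01% of filtered cells, were removed before any value was computed. Because the cells were sorted on CD11c, each share describes the sorted fraction and not the whole thymus.

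MC38 is a mouse colon carcinoma line that was implanted under the skin, so this comparison asks how thymic antigen-presenting cells differ when a tumour grows elsewhere. At 2 weeks, the tumour library held fewer pDC-like and more mature DC-like cells among dendritic cells than the PBS library. Slc15a2, which encodes a peptide transporter, was higher in all 5 classes. In the 3-week wild type tumour library, of the other batch, it lay below the PBS level in each class. Ccl5 was higher in cDC1-like and pDC-like cells. In macrophage-like cells Thbs1, Nrg1 and Spp1 were higher, and the complement list had a median below zero.

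The pDC-like share of dendritic cells went from 28.0% with PBS to 22.8% with the tumour (log2 ratio -0.30, -0.36 to -0.24) and the mature DC-like share from 28.0% to 33.7% (0.27, 0.21 to 0.32). cDC1-like cells moved from 33.2% to 31.5% (-0.07, -0.12 to -0.02), a direction that turned when mature DC-like cells were left out of the denominator (0.045), and cDC2-like cells from 10.8% to 12.0% (0.15, 0.06 to 0.25). Macrophage-like cells made up 7.09% and 8.31% of kept cells (0.23, 0.13 to 0.33). T lineage-like cells, led by Cd3d, Cd3g, Tcf7 and Satb1, went from 1.86% to 4.09% (1.14, 0.96 to 1.32). Their median depths were 1391 and 1421.5 UMIs, below those of each compared class in these libraries. B cell-like cells stood at 0.704% and 0.819% and NK or ILC-like cells at 0.582% and 0.673%, with intervals of the ratio that span no difference. Ccr9 changed little in pDC-like cells (0.05) and cDC1-like cells (0.09), and was lower in cDC2-like (-0.26) and macrophage-like cells (-0.50). In macrophage-like cells pDC marker RNA also went from 1.45% to 0.940% of its pDC-like level, which would bring 11.4 of 14.2 CPM of Ccr9 with PBS and 7.62 of 10.0 with the tumour, so the lower value is not read as a change within these cells.

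**Figure D2:**
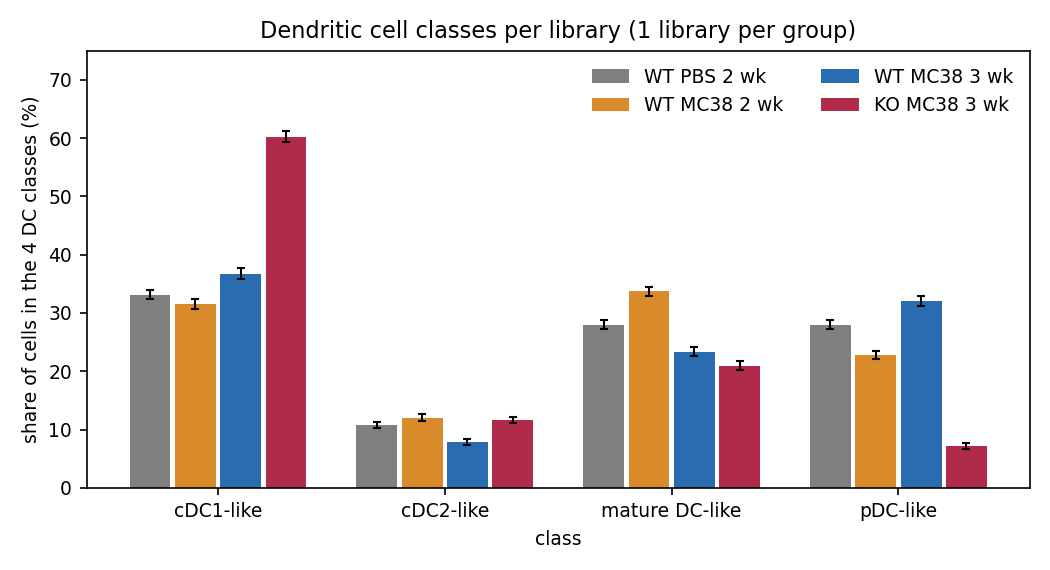
Share of the 4 dendritic cell classes among dendritic cells, in percent, in each library. Bars are shares of cells with exact 95% binomial intervals, for 1 library per group.

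Slc15a2 rose from 4.04 to 20.1 CPM in cDC1-like cells (log2 ratio 2.31, 2.12 to 2.52), from 11.7 to 47.7 in cDC2-like cells (2.03) and from 4.51 to 23.9 in pDC-like cells (2.41). As folds, Slc15a2 was 4.97, 4.08, 4.18, 5.30 and 4.30 times as high with the tumour in cDC1-like, cDC2-like, mature DC-like, pDC-like and macrophage-like cells. The 3-week wild type tumour library, of the other batch, held 1.63, 5.31, 2.12, 1.11 and 1.62 CPM in the same order. Each lay below the PBS level, so a higher level with the tumour was not seen in both wild type tumour libraries. The chemokine gene Ccl5 went from 29.3 to 58.7 CPM in cDC1-like cells (1.00, 0.92 to 1.09) and from 64.3 to 134 in pDC-like cells (1.05). Mid1, which encodes a ubiquitin ligase bound to microtubules, rose from 12.4 to 21.5 in cDC1-like (0.79) and from 11.8 to 24.1 in pDC-like cells (1.02). Rsrp1 dropped from 157 to 101 CPM in cDC1-like (-0.64) and from 213 to 132 in pDC-like cells (-0.69). Cxcl10, an interferon-induced chemokine gene, went from 63.8 to 37.5 in cDC2-like cells (-0.77), and this turned to 0.51 when each library was clustered on its own. No gene of mature DC-like cells met the rule for named genes.

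Macrophage-like cells of the tumour library held more Thbs1 (thrombospondin 1; 13.8 to 36.4 CPM, log2 ratio 1.40), Nrg1 (neuregulin 1; 20.6 to 50.5) and Spp1 (osteopontin; 33.0 to 62.3, 0.92). Vegfa (0.87), of the glycolysis and hypoxia list, and the cell cycle inhibitor gene Cdkn1a (0.65), of the apoptosis list, were also higher. Neither gene is named by the rule, and neither list met the rule for description in these cells. Ccl8 went from 89.3 to 40.4 CPM (-1.15) and Pf4, which encodes platelet factor 4, to 51.3 CPM (-0.93). Retnla went from 52.9 to 25.3 (-1.06), but 60.5% of its tumour-library counts came from 1 cell, and with each library clustered on its own the ratio was 4.18. The inflammatory and NF-kB list had a median of 0.27 (counting interval 0.15 to 0.31, percentile 100), with 10 of 15 members above zero: Il1rn 0.42, Il1b 0.41 and Nlrp3 0.40, against Tnf at -0.46. The interferon gamma list had a median of -0.23, with 15 of 16 members below zero, among them Gbp7 (-0.30), Cxcl10 (-0.27) and Socs1 (-0.26). Of the complement genes, 9 of 10 lay below zero (median -0.20), among them C3ar1 (-0.41), C1qa (-0.30), C1qc (-0.30) and C1qb (-0.25).

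In pDC-like cells the maturation and costimulation list had a median of 0.39 (0.20 to 0.46, percentile 100), with 12 of 15 members above zero. Ccr7 (0.52), Fscn1 (0.40) and Marcksl1 (0.36) were higher and Tnfsf9 lower (-0.43). Ccr7 and Fscn1 are also markers of mature DC-like cells, whose share of kept cells went from 21.4% to 24.4%. Over all libraries Ccr7 stood at 27.6 and 30.7 CPM in pDC-like clusters 2 and 3 and at 3241 to 3432 in mature DC-like clusters. RNA carried over from mature DC-like cells was not tested, so a change within pDC-like cells is left open. Chemokine ligands had a median of 0.68 with 9 of 12 members above zero, while their summed counts went the other way (-0.05), because the abundant Ccl4 (-0.07) and Ccl3 (-0.25) were lower as Ccl5 rose. In pDC-like cells without a UMI of 6 T cell genes the chemokine median was 0.076. Coinhibitory and tolerance-linked genes had a median of 0.22 and a sum of -0.05, with Vsir at 0.20 and Lgals9 at -0.28, and the median turned to -0.10 with thinned cells. Beside these groups, the dissociation and heat-shock stress list stood at 0.18 in cDC1-like cells, where Hspe1 (0.46), Hspd1 (0.41) and Hsp90aa1 (0.39) were higher, at 0.18 in mature DC-like and at 0.17 in both pDC-like and macrophage-like cells, and at -0.02 in cDC2-like cells, where its sum went from 10877 to 10179 CPM. The thymocyte carry-over list had positive medians of 0.45, 0.29, 0.38 and 0.45 in cDC1-like, cDC2-like, mature DC-like and macrophage-like cells and negative sums of -0.19, -0.38, -0.21 and -0.22, since its most abundant members were lower: Cd8a at -0.25 in cDC1-like cells and Cd4 at -0.38 in macrophage-like cells. A Cd8a UMI was held by 3031 of 4788 cDC1-like cells with PBS and 2326 of 4038 with the tumour. Whether these sums are carry-over or expression by the cells themselves was not tested.

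**Figure D3:**
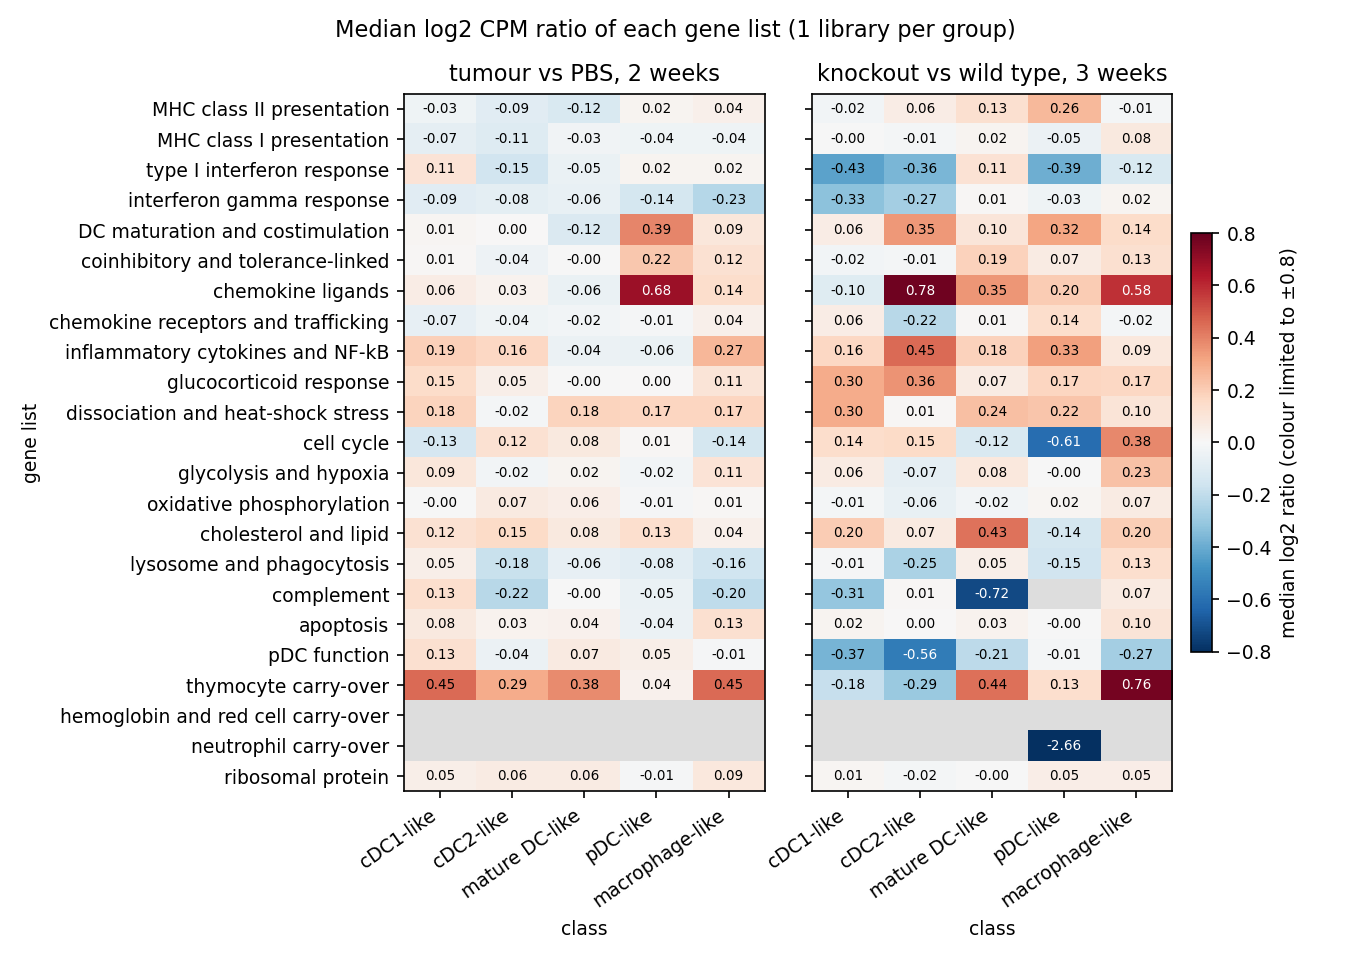
Median log2 CPM ratio of each gene list (vertical axis) in each cell class (horizontal axis), for tumour against PBS at 2 weeks (left) and knockout against wild type at 3 weeks (right), 1 library per group. Color and printed value give the median over measured members, and grey marks lists with fewer than 5 measured members.

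At 3 weeks, Ccr9 knockout and wild type mice, both bearing MC38 tumours, were compared within 1 batch. The largest difference in composition was the pDC-like share, 4.49-fold lower in the knockout library, while the cDC1-like share was 1.64-fold higher. The type I interferon list had a median below zero in cDC1-like, cDC2-like and pDC-like cells of the knockout library, although its sum was level in pDC-like cells. With libraries clustered separately its median turned in cDC2-like cells and was -0.096 in cDC1-like cells. The inflammatory and chemokine lists had medians above zero in cDC2-like cells. The cholesterol and lipid list had a positive median in mature DC-like cells, and Il1rapl1 was lower in cDC1-like, mature DC-like, pDC-like and macrophage-like cells. A genotype difference cannot be separated from a difference between the mice of these libraries.

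Of dendritic cells, pDC-like cells made up 32.1% (31.2 to 33.0) in wild type and 7.15% (6.68 to 7.63) in the knockout (log2 ratio -2.17, -2.27 to -2.06), and of all kept cells 25.2% and 5.76%. The cDC1-like share went from 36.7% to 60.3% (0.71, 0.67 to 0.76). The cDC2-like share went from 7.88% to 11.6% (0.56, 0.45 to 0.68), falling to 0.046 at Leiden resolution 2, and the mature DC-like share from 23.3% to 20.9% (-0.16, -0.23 to -0.09), turning to 0.040 with libraries clustered separately. With pDC-like cells out of the denominator the cDC1-like ratio was 0.26 and the mature DC-like ratio -0.61. Within the cDC1-like class, cluster 11, led by Mt3, Cd207 and Itgae, held 18.8% of wild type and 7.57% of knockout cells, and cluster 4, led by Nr4a2, held 18.1% and 24.1%. Of all kept cells, macrophage-like cells made up 3.72% and 2.77% (-0.42), T lineage-like cells 0.872% and 1.99% (1.19), NK or ILC-like cells 0.777% and 0.225% (-1.79, -2.36 to -1.22) and B cell-like cells 1.16% and 0.711% (-0.71).

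In cDC1-like cells S100a10, which encodes a calcium-binding family partner of annexin A2, went from 49.4 to 109 CPM (log2 ratio 1.14) and the monocyte chemokine gene Ccl2 from 15.7 to 34.4 (1.13). Gm4316 went from 8.69 to 21.2 (1.28), turning to -0.80 with libraries clustered separately. Il1rapl1, of the interleukin 1 receptor family, went from 33.5 to 9.41 CPM (-1.83) and Spint1, which encodes a serine protease inhibitor, from 77.5 to 22.8 (-1.77). The type I interferon list had a median of -0.43 (-0.49 to -0.39, percentile 0), outside the -0.06 to 0.07 that held 95% of random lists, with 20 of 21 members below zero. Ifi44 (-0.74), Oasl1 (-0.73), Oas1a (-0.68) and Ifi27l2a (-0.59, 394 to 262 CPM) led the list, whose median was -0.096 with libraries clustered separately. Of the interferon gamma list 13 of 16 members lay below zero (median -0.33; Irf1 -0.33, Irgm1 -0.33), with Cxcl10 above it (0.38), and this median turned to 0.027 with separate clustering. All 14 members of the pDC function list lay below zero (median -0.37), 13 of them past their interval, with Ptprs at -0.32, Irf7 at -0.30 and Bst2 at -0.23, where pDC marker RNA stood at 0.496% of its pDC-like level in wild type and 0.222% in the knockout. Irf7 and Bst2 are also members of the type I interferon list, so the 2 lists overlap. All 17 stress genes lay above zero (0.30), 16 of them past their interval, with Zfp36 at 0.58, Ier3 at 0.55, Atf3 at 0.53 and Jun at 0.48. Beside them stood glucocorticoid-response genes (0.30; Dusp1 0.55, Mt1 0.48, Sgk1 0.35) and cholesterol and lipid genes, whose median of 0.20 (Insig1 0.45, Hmgcs1 0.29) came with a sum of -0.08 (Cd36 -0.26).

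In cDC2-like cells Slc15a2 went from 5.31 to 34.2 CPM (log2 ratio 2.69), Ccl3 from 41.4 to 101 (1.29) and Wdsub1 from 7.84 to 21.4 (1.45). Over all classes Slc15a2 was 3.98, 6.44, 3.35, 6.17 and 7.51 times as high in the knockout in cDC1-like, cDC2-like, mature DC-like, pDC-like and macrophage-like cells. The wild type library at 3 weeks held 1.63, 5.31, 2.12, 1.11 and 1.62 CPM of it in the same order, below the PBS library of the other batch (4.04, 11.7, 3.53, 4.51 and 4.06). Ly6c2, a gene of monocytes and pDC, went from 382 to 72.1 CPM (-2.41). Jchain went from 206 to 5.74 CPM (-5.17), a value set by 1 wild type cell with 99.9% of the counts, and without the cell richest in Jchain in each library the ratio was 2.28. Chemokine ligands had a median of 0.78 (0.63 to 0.89, percentile 100), with Cxcl2 (16.9 to 41.7 CPM) and Ccl22 (0.99) higher and Ccl5 lower (-2.24), although 1 wild type cell held 46.7% of the Ccl5 counts. The chemokine median was 0.17 with doublets kept, 0.18 with thinned cells and 1.63 with libraries clustered separately.

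Inflammatory and NF-kB genes of cDC2-like cells had a median of 0.45, with 12 of 14 members above zero: Il1rn 1.07, Il1b 0.90 (1463 to 2726 CPM) and Nfkbia 0.83. Of the maturation list 13 of 17 members lay above zero (0.35; Cd40 0.63, Ccr7 0.52, Cd83 0.51, Cd80 0.47). Of type I interferon genes 21 of 22 lay below zero (-0.36), 16 of them past their interval (Ifi27l2a -0.66, Xaf1 -0.54, Irf7 -0.54), and this turned to 0.74 with libraries clustered separately. Glucocorticoid-response genes had a median of 0.36, with 9 of 13 members above zero and 3 lower past their interval (Dusp1 0.73, Mt2 0.68, Txnip -0.86), turning to -0.21 under the same setting. The pDC function list had a median of -0.56, with 11 of 14 members below zero, led by the transcription factor gene Irf8 (-2.16, 83.6 to 18.8 CPM), Havcr1 (-1.13), Lair1 (-0.91) and Siglech (-0.86), while pDC marker RNA in these cells went from 2.43% to 1.40% of its pDC-like level, so a change within cDC2-like cells is left open. Lysosome and phagocytosis genes had a median of -0.25, with 13 of 17 members below zero, 10 of them past their interval, and 3 higher past it (Grn -0.51, Timd4 -0.40). Chemokine receptors had a median of -0.22 and a sum of 0.01, with Ccr1 lower (-1.93) and Ccr7 higher, and the median was 0.013 with thinned cells. The stress list stood at 0.01 (-0.04 to 0.04) in these cells, with 9 of 17 members above zero and a sum of 0.16 (Ier3 0.80, Hspa1b -0.61).

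Mature DC-like cells of the knockout library held more Fdps (36.3 to 93.4 CPM, log2 ratio 1.36) and Fdft1 (24.8 to 51.5, 1.06), which encode enzymes of the cholesterol pathway, and more Nmrk1, a nicotinamide riboside kinase gene (19.8 to 48.5). The cholesterol and lipid list had a median of 0.43 with 9 of 15 members above zero and 4 lower past their interval, Hmgcs1 at 1.00, Insig1 at 0.96 and Apoe at -0.80. Grid1, a glutamate receptor gene, went from 22.9 to 2.29 CPM (-3.33), Il1rapl1 from 50.4 to 13.3 (-1.92) and 2610528A11Rik from 114 to 39.3 (-1.53). Chemokine ligands had a median of 0.35 (Ccl4 0.79, Cxcl9 0.73, Cxcl10 0.54) and a sum of -0.09. Complement genes, together at 46.0 and 30.3 CPM, had a median of -0.72, which was -0.36 without a cell filter. Complement genes and Apoe lead the macrophage-like cluster, whose share was also lower in this comparison, so the complement value is not read as a change within mature DC-like cells. The stress list stood at 0.24 with 15 of 17 members above zero (Ier3 0.70, Zfp36 0.54), and the thymocyte list at 0.44 with a sum of -0.00 (Cd8b1 -0.17).

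The 819 pDC-like cells of the knockout library held more Gm30411 (4.10 to 45.1 CPM, log2 ratio 3.46), Rnase4 (4.92 to 36.3, 2.88) and the adhesion receptor gene Adgrg5 (9.01 to 44.6, 2.31), and less Gm42047 (30.9 to 3.17, -3.29) and Il1rapl1 (45.3 to 9.99, -2.18). MHC class II genes had a median of 0.26, with 11 of 12 members above zero, 9 of them past their interval, and 1 lower past it, led by H2-Eb1 (0.50), Ciita (0.44) and H2-Aa (0.44). The maturation list stood at 0.32 (Ccr7 1.04, Cd83 0.86, Nfkb2 0.47). The inflammatory list stood at 0.33 (Tnf 0.34, Nfkbia 0.34), and its largest ratio, Il1b at 2.31, drew 51.0% of its knockout counts from 1 cell. Type I interferon genes had a median of -0.39 with 15 of 19 members below zero (Oasl1 -0.87, Usp18 -0.55, Irf7 -0.50, Ifi27l2a -0.48) and a sum of -0.02. Cell cycle genes had a median of -0.61 with 19 of 20 members below zero (-0.98 to -0.45), led by Stmn1 (-1.15, 45.8 to 20.7 CPM), and this turned to 0.48 with doublets kept. Cluster 26, the cycling pDC-like cells, held 30 wild type and 2 knockout cells, and without it the median was -0.26 (-0.42 to 0.03). The stress list stood at 0.22, with Fosb at 0.89 and Fos at 0.74. Neutrophil carry-over genes had a median of -2.66, and S100a9, at 22.7 CPM in wild type and no count in the knockout, had a log2 ratio of -4.96 at 3 counts and was at least 25.2-fold lower with counting error, although its wild type counts came from 4 cells, 1 of which held 70.8%.

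In macrophage-like cells the knockout library held more Rnase2a, an eosinophil-associated ribonuclease gene (6.47 to 92.0 CPM, log2 ratio 3.83), Retnla (50.9 to 452, 3.15) and Ccl24, which encodes eotaxin 2 (9.71 to 62.4, 2.68). The knockout counts of Retnla came from 20 of 394 cells and those of Rnase2a from 48. Il1rapl1 went from 78.1 to 19.3 CPM (-2.01) and Cd209d from 35.8 to 6.90 (-2.38), although 52.9% of wild type Cd209d counts came from 1 cell and the ratio was 0.12 with thinned cells. Chemokine ligands had a median of 0.58 (Ccl22 1.18, Ccl17 0.78, and Cxcl2 from 117 to 249 CPM) and a sum of 0.02, and the median was 0.23 with the stricter cell filter. In the knockout library 1 cell held 30.9% of the Ccl22 counts and 1 cell 30.9% of the Ccl17 counts. Without the cell richest in the gene in each library, the ratios were 0.95 for Ccl22 and 0.40 for Ccl17. Cell cycle genes had a median of 0.38 (0.17 to 0.53) with 17 of 20 members above zero, 6 of them past their interval (Ccnb2 0.94, Mki67 0.66), and glycolysis and hypoxia genes a median of 0.23 (Pgk1 0.43, P4ha1 -0.65). The pDC function list had a median of -0.27 with a counting interval that spans zero (-0.35 to 0.07) and 8 of 13 members below zero (Siglech -1.43, Lag3 -0.57, Tlr9 0.41). The thymocyte list had a median of 0.76 and a sum of -0.09 (Cd4 -0.25), and its median was -0.28 with thinned cells.

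Chemokine receptor genes near Ccr9 on chromosome 9 also differed between the 3-week libraries. Ccr1 was lower in the knockout in cDC2-like (log2 ratio -1.93) and macrophage-like cells (-1.50). Ccr2 was lower in cDC1-like (-0.58) and higher in pDC-like cells (0.86), whereas Xcr1 was level in cDC1-like cells (-0.00). Sacm1l, which encodes a lipid phosphatase, was lower in cDC1-like (-0.46), mature DC-like (-1.06) and pDC-like cells (-0.96). Lars2, the mitochondrial leucyl-tRNA synthetase gene, was lower in all 5 classes (-0.55, -0.33, -0.50, -0.40 and -0.72). In macrophage-like cells Lars2 stood at 1272 CPM in the knockout and 2098 in the 3-week wild type library. That knockout level lay between those of the PBS (1151) and 2-week tumour (1323) libraries of the other batch. Fyco1 was higher in cDC1-like (0.31), mature DC-like (0.73) and pDC-like cells (0.35), lower in cDC2-like cells (-0.32, -0.59 to -0.04) and at 0.49 in macrophage-like cells (-0.02 to 1.00). Lztfl1, which lies within the span of Ccr9 (123678439 to 123784330 on GRCm38), was at -0.31 in cDC1-like, -0.22 in pDC-like, 0.17 in mature DC-like (0.0024 to 0.34), 0.36 in macrophage-like (0.05 to 0.68) and 0.16 in cDC2-like cells, the last with an interval that spans zero (-0.02 to 0.35).

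Tumour-bearing wild type mice were also compared between 3 and 2 weeks, where batch and week cannot be told apart. The 3-week library held a larger pDC-like share and smaller mature DC-like and macrophage-like shares. Anks1b was lower in all 5 classes, and the chemokine ligand list had a median below zero in each class. A shift in scaling of 0.078, 0.095, 0.14, 0.12 and 0.14 log2 units in cDC1-like, cDC2-like, mature DC-like, pDC-like and macrophage-like cells sits under these ratios, so that each is to be read against it.

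From 2 to 3 weeks the pDC-like share of dendritic cells went from 22.8% to 32.1% (log2 ratio 0.49), cDC1-like from 31.5% to 36.7% (0.22), cDC2-like from 12.0% to 7.88% (-0.61) and mature DC-like from 33.7% to 23.3% (-0.53). With libraries clustered separately the cDC1-like ratio turned to -0.21 and the mature DC-like ratio to 0.11. Macrophage-like cells went from 8.31% to 3.72% of kept cells (-1.16) and T lineage-like cells from 4.09% to 0.872% (-2.23). Anks1b, which encodes a scaffold protein, had ratios of -4.91, -5.74, -4.32, -4.88 and -5.16 in cDC1-like, cDC2-like, mature DC-like, pDC-like and macrophage-like cells. Hist2h2ac was higher in cDC1-like cells (1.76), Camk2b in mature DC-like (1.74) and pDC-like cells (1.59) and Ptprm in macrophage-like cells (2.49). Jchain in cDC2-like cells (11.61) again rested on 1 cell, and was -0.21 with libraries clustered separately. Chemokine ligands had medians of -1.15, -0.67, -0.44, -1.29 and -0.54 in cDC1-like, cDC2-like, mature DC-like, pDC-like and macrophage-like cells, and the stress list -0.33, -0.27, -0.45 and -0.65 in the 4 dendritic cell classes. Cell cycle genes had medians of -0.91 in pDC-like and -0.80 in macrophage-like cells, and lysosome genes 0.36 and 0.29. The thymocyte list had a median of -1.14 in cDC1-like cells and a sum of the other sign (0.30; 181 to 223 CPM).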

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

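No paired analysis was possible because the results come from no test and each group has 1 library, so that the batch shared by libraries compared at the same week gives 1 pair and no repeat of it. Of a leading set of results, 198 values stayed, 58 moved and 5 changed sign under another setting. Of the other results 813 stayed, 146 moved and 20 changed sign. The leading set included the dendritic cell class shares, Ccr9 in the knockout comparison and some lists, such as type I interferon in cDC1-like cells. Several results that open a comparison were counted among the others. These include the type I interferon and inflammatory lists in cDC2-like cells and the cholesterol list in mature DC-like cells. Values are log2 ratios, shares are of dendritic cells unless stated, and the cause was not tested for any of them.

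With each library clustered on its own, the tumour ratio of the cDC2-like share was 0.57 and of the mature DC-like share 0.096. In the knockout comparison the shares were 0.43 for cDC1-like, 1.06 for cDC2-like, 0.040 for mature DC-like (a change of sign) and -1.80 for pDC-like cells, and from 2 to 3 weeks -0.21 for cDC1-like and 0.11 for mature DC-like cells, with both signs changed. The knockout type I interferon median was -0.096 in cDC1-like and changed sign in cDC2-like cells (0.74), as did the interferon gamma median in cDC1-like (0.027) and the glucocorticoid median in cDC2-like cells (-0.21). The chemokine ligand median in cDC2-like cells was 1.63. Signs also changed for Gm4316 (-0.80), Cxcl10 (0.51), Retnla in the tumour comparison (4.18) and Jchain against knockout (3.87) and against 2 weeks (-0.21).

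At resolution 0.5 the cDC2-like share was 0.12 in the knockout comparison and -0.37 from 2 to 3 weeks. At resolution 2 it was 0.046 and -0.31, the cDC1-like knockout ratio was 0.78 and Jchain changed sign (2.34). With the stricter filter the cDC2-like values were 0.058 and -0.32, and the chemokine ligand median in knockout macrophage-like cells was 0.23. Without a filter the knockout shares were 0.78 for cDC1-like, 0.052 for cDC2-like and -0.046 for mature DC-like cells, and from 2 to 3 weeks 0.17 for cDC1-like and -0.31 for cDC2-like cells. The chemokine ligand medians were then 0.60 in cDC2-like and 0.38 in macrophage-like cells, and the complement median in mature DC-like cells -0.36.

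With doublets kept the mature DC-like knockout ratio was -0.044, and from 2 to 3 weeks the ratios were 0.14 for cDC1-like, -0.43 for mature DC-like and 0.39 for pDC-like cells. The chemokine ligand medians were 0.17 in knockout cDC2-like and 0.29 in macrophage-like cells, the cell cycle median in pDC-like cells changed sign (0.48), and so did the thymocyte median in macrophage-like cells (-0.23).

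With cells thinned the chemokine ligand median in cDC2-like cells was 0.18. Signs changed for chemokine receptors in cDC2-like cells (0.013), coinhibitory genes in tumour pDC-like cells (-0.10), thymocyte genes in knockout macrophage-like cells (-0.28) and Cd209d (0.12). Ccr9 against knockout was then -6.07 in cDC2-like, -9.26 in pDC-like and -3.28 in macrophage-like cells, each with no knockout count and so set at the floor of 3 counts, so that the value follows the number of counts left. With cells weighted equally the chemokine ligand median in cDC2-like cells was 0.62 and the thymocyte median in macrophage-like cells -0.26. In cells without a T cell gene UMI the chemokine ligand median in tumour pDC-like cells was 0.076, Ccr9 in pDC-like cells -8.83 (at the same floor), and the thymocyte median changed sign in knockout mature DC-like (-0.24) and macrophage-like cells (-0.20). At 100 counts per member it changed sign in the same classes (-0.0089 and -0.25).

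With mature DC-like cells out of the denominator the tumour ratios were 0.045 for cDC1-like (a change of sign), 0.27 for cDC2-like and -0.18 for pDC-like cells, the cDC1-like knockout ratio was 0.67, and from 2 to 3 weeks the ratios were 0.011 for cDC1-like, -0.82 for cDC2-like and 0.29 for pDC-like cells. With pDC-like cells out, cDC1-like, cDC2-like and mature DC-like ratios were -0.17, 0.053 and 0.16 with the tumour, 0.26, 0.11 and -0.61 in the knockout and 0.41, -0.43 and -0.34 from 2 to 3 weeks. As shares of every kept cell, the tumour ratios were -0.15 for cDC1-like, 0.19 for mature DC-like and -0.38 for pDC-like cells, and those from 2 to 3 weeks 0.34, -0.49, -0.41 and 0.61 for cDC1-like, cDC2-like, mature DC-like and pDC-like cells. Without the cell richest in the gene, Jchain against knockout changed sign (2.28).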

Other observations

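Several clusters without a class differed between the 3-week libraries. Cluster 12, led by Ly6c2, Cd209d, Clec10a and Tcf4 and so carrying genes of both cDC2 and pDC, went from 3.23% of wild type to 0.858% of knockout cells (log2 ratio -1.91, -2.20 to -1.63), with Ly6c2 at 4224 and 2674 CPM and Siglech at 701 and 475. Cluster 15, led by Cxcl9, Oasl1, Isg15 and Cd40, went from 1.31% to 2.79% (1.09). Cluster 7, led by Ifitm3, Il1r2, Il1b and Mmp12, went from 5.03% to 7.25% (0.53), with Il1b at 2035 and 2895 CPM. The NK or ILC-like cluster, led by Gzmc, Xcl1 and Nkg7 and holding Ncr1 at 198 and 187 CPM, was the class after pDC-like cells with the largest fall. Cluster 22, pDC-like cells with few UMIs led by Mctp2, Grm8 and Runx2, went from 1.76% to 0.204% (-3.11).

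Cluster 24 was led by Nrg1, Dpp10, Prg2 and Prg3 and held the autoimmune regulator gene Aire at 53.6, 66.2, 98.4 and 80.7 CPM in the PBS, 2-week tumour, 3-week wild type and knockout libraries. Its share of kept cells was 1.06% in wild type and 0.704% in the knockout at 3 weeks (-0.60, -0.96 to -0.23). Of the marker lists, that of the T lineage had the most markers in cluster 24, with 7, and Cd3e stood at 42.4 CPM there. Over all libraries Aire was also at 52.3 CPM in the B cell-like cluster 20, 43.3 in mature DC-like cluster 1 and 31.1 in unnamed cluster 17.

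The pDC-like share was lower in the knockout library. Placement in other clusters of knockout pDC that kept their marker genes is argued against by the share of kept cells with pDC marker genes at 0.3% or more of UMIs. This share was 4.03-fold lower (3.77 to 4.30), at 28.3% and 7.04%, with 2.62% and 1.46% of cells near the threshold. Loss of pDC through the cell filter or the doublet call is argued against by the same share over every barcode, 3.94-fold lower (3.72 to 4.19); this test was chosen after the share had been seen. Of kept cells outside the pDC-like class, 4.24% in wild type and 1.35% in the knockout reached the threshold. Both tests use the genes that name the class, so knockout pDC that had lost these genes would be missed, which is left open. The pDC-like cells may be fewer in the thymus, lost in sorting on CD11c or removed before the knockout matrix was written again, which these barcodes cannot show, and all 3 remain open, as does the variation between mice.

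The type I interferon list was lower in knockout cDC1-like cells. Free RNA from pDC made up 0.549% (0.415 to 0.941) of the fall of the median member, from a free share of 0.496% in wild type and 0.222% in the knockout, and with cells thinned to 3000 UMIs the median was -0.40 (-0.47 to -0.29), so both are argued against as causes. A different mix of clusters fits cluster 0, whose own median was -0.062 (-0.13 to -0.02), but not clusters 4, 10, 13 and 18, where the highest median was -0.36 (-0.44 to -0.31), the others being -0.37, -0.80 and -0.61; the latter test was added after the former. Cluster 11, with the highest interferon list sum (4192 and 4514 CPM) and a median of 0.03, made up less of the knockout class, and the clusters themselves were drawn with interferon genes among the variable genes. The fall may therefore be partly a change of mix and partly a change within clusters, and the share of each stays open, also because cluster 15, led by interferon-induced genes and holding Xcr1 at 179.9 CPM, lies outside the class and was larger in the knockout library. With each library clustered on its own the median of the list was -0.096, so the size of the fall depends on which cells are called cDC1-like.

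Genes beside Ccr9 differed in the knockout library. A strain segment carried with the knockout allele is left undecided by genes within 10 Mb. Their median absolute log2 ratio lay at percentiles 86.5, 95.2, 21.2, 84.7 and 55.8 of random lists in cDC1-like, cDC2-like, mature DC-like, pDC-like and macrophage-like cells. Of these, 4 of 5 lay below 90, the bound set beforehand against a segment. The middle of the 5 values, 84.7, had an interval of 27.4 to 99.1 from resampled genes, which reaches past that bound. This interval follows whichever class is in the middle in each redraw, and was added after the value. Genes within 0.5 Mb lay at percentiles 100, 99.98, 99.72, 100 and 99.9 in the same order of classes, the middle value with an interval of 99.6 to 100. This distance was chosen after these genes had been seen, so the values restate the pattern and support no cause. Whether the lower level of Ccr1 comes from the altered locus or from the loss of the receptor stays open, and the structure of the knockout allele is not given in the labels.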
